A study of Arabidopsis thaliana with 15 samples.

How the data were processed

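Polyadenylated RNA was selected, per the labels' protocols, and sequenced from 2-week-old Arabidopsis thaliana seedlings of the wild type and of the eds4 mutant, grown side by side on agar medium at 22 °C in continuous white light of 50 µmol per square metre per second. EDS4 (AT5G51200) encodes NUP205, a scaffold protein of the nuclear pore complex; this identity is background knowledge, and the reference annotation lists the locus as a nuclear pore complex protein. There were 2 experiments. The profiling experiment held whole seedlings of the wild type (n = 4) and of eds4 (n = 3), extracted with a column kit. The distribution experiment held whole seedlings ("total", n = 2 per genotype) and nuclei purified by fluorescence-activated sorting (n = 2 per genotype), extracted with phenol; the labels of the nuclei call their molecule nuclear RNA. Per the labels' protocols, both were made into libraries with an Illumina TruSeq kit, with random hexamer priming and 12 cycles of PCR, and sequenced in pairs on a HiSeq 1500. The labels state replicates but not whether they were separate cultures or pools of plants, so p-values measure only the spread between these samples, part of which may be technical.

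The authors deposited 3 tables of raw read counts per locus, which together held 15 libraries and listed the same 33602 loci with coordinates. The submitters' processing notes name TopHat2 2.1.1 for alignment, SAMtools 1.3 and the TAIR10 genome build. The program that counted reads, its strand setting, its treatment of reads with several matches and the annotation release are not given in the sources used here. The kit does not record strand, so reads of overlapping loci on opposite strands cannot be told apart; 489 loci listed an overlapping locus. The deposited counts were whole numbers with a different total in every library, as unnormalised counts are. Each library was placed by its column name, which matched the description in its label, and 0 columns belonged to other samples. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 11.1 to 115), so no library is a copy of another of its group. Libraries of different groups were not compared in this way.

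Library totals were 37277300 to 51059295 counts in wild type seedlings and 39474734 to 45343833 in eds4 seedlings. In the distribution experiment they were 31168662 to 31745372 in wild type total RNA, 22805360 to 31586867 in eds4 total RNA, 15291096 to 19594301 in wild type nuclei and 12393243 to 21786898 in eds4 nuclei. The nuclei were therefore measured at the lowest depth. Counts were expressed as CPM, a rate per library size, on library sizes scaled by the trimmed mean of M values (TMM). Scaling of this kind sets the bulk of genes to no change, so a general retention of RNA in the nucleus would not be seen; every nuclear-to-total ratio is relative to the typical gene.

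Genes were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, after filterByExpr by group and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. The 7 profiling libraries were fitted alone. All 8 libraries of the distribution experiment were fitted together with a mean per group, which pools the estimate of spread. They gave nuclei against total RNA in each genotype, the difference of these ratios between genotypes (an interaction term), and eds4 against wild type in total RNA and in nuclei. The genotype effect was also compared between experiments in a fit of the 11 whole-seedling libraries. Of the values at the EDS4 locus, the unadjusted p is also given, because that locus was named beforehand.

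There were 27 fixed gene lists: pathways, complexes, RNA classes and markers of the cell types a seedling holds. Lists with at least 5 measured members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, then with an estimated correlation. Camera asks whether a list moved relative to the other genes. With an estimated correlation, 0 of the called lists passed in any of the 6 comparisons tested. The fry test, which asks whether the members of a list move on balance one way, was an alternative. Members that passed are counted after adjustment over all genes tested, and again adjusted over the list alone. Genes were named by a rule: EDS4; the 10 largest rises and 10 largest falls in seedlings (5 and 5 in other comparisons) among genes with an adjusted p under 0.05, an average log2 CPM of at least 1 and groups that did not overlap; and up to 4 members of each list with the smallest adjusted p. The tests, lists, naming rule and most alternatives were fixed before the data were examined; alternatives and genes chosen later are named as such.

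Where a group held 0 counts of a gene, a fold change is given as a lower limit against a floor of 3 counts over the group's summed depth. Where it held 1 to 3 counts, the ratio is given with its 95% exact interval. Both cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Symbols, products and RNA classes came from the RefSeq annotation of TAIR10.1, which matched 32835 of the 33602 loci (767 had no match); coordinates are those of the deposited tables, in TAIR10. Transcripts of named genes were searched against all others with BLAST+ 2.17.0, and a near-identical copy was one with at least 95% identity over at least 50% of the query. Organelle genes were not searched. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

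The steps were tested on simulated counts with the library sizes of these samples and 1 mean per gene, the same in every group. In 1 group 67 genes were then changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. In the real data 6582 and 6357 genes passed for nuclei against total RNA in the wild type and eds4, so the recovery simulated for these comparisons need not hold. In the seedling comparison, 37.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 12 false calls among 159, over 22055 genes. The distribution experiment gave less. For 4-fold changes, recovery was 86.4% in total RNA (21072 genes), 63.6% in nuclei (21079 genes), 60.6% and 59.1% for nuclei against total RNA in the wild type (21060 genes) and eds4 (21079 genes), and 16.7% for the interaction (21079 genes). No 2-fold change was recovered for the interaction (0%), and 4.48% were in nuclei. For the difference between experiments, 84.8% of 4-fold and 25.4% of 2-fold changes were recovered (22375 genes). False calls there were 8 among 82. They were 11 among 73 in total RNA, 3 among 48 in nuclei and 2 among 13 for the interaction. For nuclei against total RNA they were 2 among 44 in the wild type and 2 among 42 in eds4.

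The alternatives were size factors of DESeq2 1.42.0 in the edgeR fit, DESeq2's own test, limma-voom, no filter on low counts, organelle genes left out, a minimum change of 0.58 on the log2 scale, a fit of only the groups compared, a fit of all whole-seedling libraries, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a term for replicates 1 and 2 against 3 and 4 in seedlings, replicates 1 and 2 alone, the 4 nuclear rRNA loci left out, and only replicate 1 of each nuclei group.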

Results

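RNA of 15 libraries was counted over 33602 loci. They held whole seedlings of the wild type (n = 4) and of eds4 (n = 3) in a profiling experiment. A distribution experiment held whole seedlings and sorted nuclei of both genotypes (n = 2 per group). The first asked which transcripts differ in the mutant of a nuclear pore protein, the second how transcripts of sorted nuclei compare with those of whole seedlings. Which cells gave the nuclei was not measured, so a nuclear-to-total ratio can also reflect a different mix of cells. Library totals lay between 37277300 and 51059295 counts in the profiling experiment and between 12393243 and 31745372 in the distribution experiment. The 4 nuclear rRNA loci took 0.224 to 0.356% of counts in seedlings of the profiling experiment, from 0.609% in total RNA, at most 1.59% in eds4 nuclei, and 2.79 and 11.2% in wild type nuclei. Chloroplast-encoded genes took 0.259 and 0.543% of counts in eds4 nuclei, 1.33 and 4.21% in wild type nuclei, and 2.05% in replicate 2 of eds4 total RNA. Replicate 2 of eds4 nuclei had 20779 genes with a count, against 22801 to 24555 in the other 14 libraries.

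The mutant locus, EDS4 (AT5G51200, chromosome 5, 20804926 to 20819592, TAIR10), was measured in every library. In whole seedlings its transcript stood at 73.4 ± 8.43 CPM (SD, n = 4) in the wild type and 35.4 ± 5.95 CPM (n = 3) in eds4. In total RNA of the distribution experiment it stood at 88.5 ± 10.3 CPM in the wild type and 35.2 ± 8.64 CPM in eds4 (n = 2 each), and in nuclei at 57.0 ± 12.1 and 61.0 ± 2.11 CPM. EDS4 fell by 1.05 on the log2 scale in eds4 seedlings (SE 0.13, adjusted p = 0.0101, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with every eds4 library below every wild type library. Without eds4 replicate 1 or 2 the adjusted p of this edgeR test was 0.0713 or 0.0679. In total RNA the log2 difference was -1.33 (SE 0.26, edgeR unadjusted p = 0.000505, adjusted p = 1), and DESeq2 gave it an adjusted p of 0.0141. In nuclei the difference was 0.10 (SE 0.26, edgeR unadjusted p = 0.712, adjusted p = 0.903). The transcript therefore separated the genotypes in whole seedlings of both experiments and not in nuclei, where it gives no check of the labels.

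**Figure D1:**
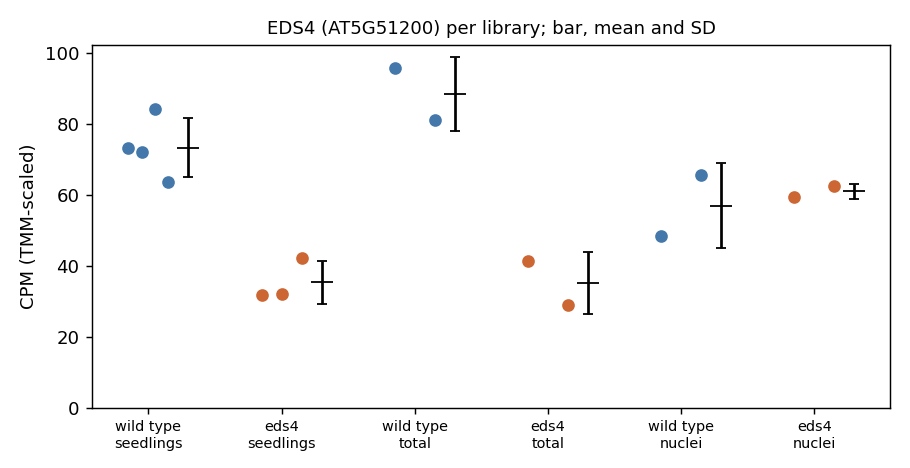
EDS4 transcript level in CPM (vertical axis, from 0) in each of the 15 libraries, by group; points are libraries, and bars are group means with SD. The eds4 means of 35.4 and 35.2 CPM in whole-seedling RNA lie below the wild type means of 73.4 and 88.5 CPM, while the nuclei means are 57.0 and 61.0 CPM.

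In eds4 seedlings, 9 of 28 photosynthesis genes, 8 of 27 circadian clock genes and 6 of 20 glucosinolate genes fell, and 3 clock genes rose. Of 33 nucleoporins 3 rose and 1 fell, and of 20 RNA export factors 2 rose. Of these 5 lists all but the nucleoporins passed camera with the preset correlation, and with an estimated correlation 0 did (lowest adjusted p = 0.102). RAP2.4 (AT1G78080, chromosome 1, 29364249 to 29366073), a transcription factor of the AP2/ERF family, rose from 161 ± 4.01 CPM in the wild type to 658 ± 43.1 CPM in eds4 (log2 change 2.03, SE 0.08). NUP98B (AT1G59660, chromosome 1, 21924693 to 21929424), a nucleoporin, rose from 8.49 ± 1.19 to 29.3 ± 2.29 CPM (1.79, SE 0.12). The light-harvesting gene LHCB2.3 (AT3G27690) fell from 878 ± 172 to 298 ± 46.5 CPM (-1.56, SE 0.18), and LNK2 (AT3G54500), a coactivator of the clock, from 348 ± 45.5 to 134 ± 22.1 CPM (-1.38, SE 0.14). Adjusted p in edgeR's quasi-likelihood test was 4.22e-05 for RAP2.4, 0.000779 for NUP98B, 0.00771 for LHCB2.3 and 0.00566 for LNK2 (n = 4 and 3).

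Of 22202 genes tested, 297 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 168 higher and 129 lower in eds4. Of these 80 changed at least 2-fold, and 3559 genes had an unadjusted p under that value. Besides RAP2.4 and NUP98B, the 10 largest rises were AT1G63530 (log2 change 2.62, SE 0.13), AT5G45990, annotated as a putative crooked neck protein (2.44), and the RNA-binding protein gene AT1G72800 (2.32). They also held the RING finger gene AT5G60250 (2.21), the kinase gene AT5G64910 (1.89), AT2G20500 (1.81), the pectin methylesterase inhibitor ATPMEPCRD (1.76) and the CCT motif gene AT1G07050 (1.76). AT2G20500 overlaps AT2G20510 and has a near-identical copy, AT2G07305, so its reads cannot be placed with certainty. The 10 largest falls were the pseudogene AT5G35935 (-3.52, SE 0.47), AT1G13650 (-2.15), the sugar transporter SAG29 (-1.95), LSM1B of the cytoplasmic mRNA decay complex (-1.85) and the pseudogene AT4G01490 (-1.81). The others were LHCB2.3, the carotene hydroxylase BETA-OHASE 2 (-1.38), LNK2, the non-coding RNA AT1G67105 (-1.36) and the kinase gene CIPK20 (-1.34). In AT5G35935, replicate 2 of the wild type lay apart at 9.54 CPM, against 4.56 CPM in the lowest of the other 3.

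The seedling libraries also differed by replicate set: the first principal component, with 38.0% of the variance, followed replicates 1 and 2 against 3 and 4 more than genotype. With a term for these sets 868 genes passed, and within replicates 1 and 2 alone 525 did; the other set held only 1 eds4 library, too few for a value of its own. Both fits were chosen after seeing the data. All 48 named genes that passed also passed with the term, and 41 of them within replicates 1 and 2. The number of genes was set in part by single libraries: it was 141, 176, 160 and 135 without wild type replicates 1 to 4, and 42, 61 and 462 without eds4 replicates 1 to 3. DESeq2 called 1047 genes, and 88 passed in a fit of all 11 whole-seedling libraries, in which 26 of the 48 named genes passed. Of the 48, 17 passed whichever library was left out, EDS4 not among them. They were RAP2.4, NUP98B, RAE1, XPO1B, CCA1, LNK1, LNK2, LNK3, TOC1, LHCB1.2, AT1G13650, AT1G63530, AT1G72800, AT2G20500, AT5G45990, AT5G60250 and ATPMEPCRD.

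Among the circadian clock genes, 8 of 27 fell and 3 rose, and 16 did not pass. The morning gene CCA1 fell from 159 ± 12.1 to 73.4 ± 8.09 CPM (log2 change -1.11, SE 0.10), LNK3 by 1.01 (SE 0.08) and LNK1 by 1.28 (SE 0.13), as did LNK2, LNK4, LHY, RVE1 and RVE8. The evening gene TOC1 rose from 52.5 ± 4.50 to 89.7 ± 2.44 CPM (0.77, SE 0.08), as did ELF4 and FKF1. Adjusted over the list alone, 10 fell and 7 rose. In edgeR's quasi-likelihood test the adjusted p was 0.00273 for CCA1, 0.00182 for LNK3, 0.00527 for LNK1 and 0.0055 for TOC1. The list as a whole lay lower (camera, adjusted p = 5.06e-05; median log2 change -0.04, mean -0.20), with adjusted p = 0.239 with an estimated correlation. Of the flowering time genes, 4 of 24 fell, all of them regulators close to the clock: COL2, CDF1 (-0.85), CDF3 (-0.63) and CDF2 (-0.69), which are kin of CONSTANS or repressors of it. Adjusted over the list alone, 5 fell and 2 rose. The list's camera adjusted p was 0.0891, with a median of 0.04, a mean of -0.01 and a test pointing down.

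Nuclear-encoded photosynthesis genes, markers of mesophyll, had 9 of 28 members lower and 0 higher (18 and 0 adjusted over the list alone). All 9 encode light-harvesting proteins, such as LHCB1.2, LHCB1.1 (-1.21), LHCA4 (-1.08) and LHCA1 (-1.13). LHCB1.2 and LHCB1.1 have near-identical copies, so reads cannot be placed with certainty between them. The list's median was -0.44 (camera, adjusted p = 3.3e-32; adjusted p = 0.239 with an estimated correlation). Of 20 glucosinolate genes, 6 fell and 0 rose (10 and 0 adjusted over the list alone), among them the regulator MYB29 (-0.75, SE 0.09) and the methionine chain elongation and core enzymes CYP79F1 (-0.74), BCAT4 (-0.68) and MAM1 (-0.67). BCAT4 stood at 180 CPM in wild type replicate 3, against 215 to 217 CPM in the other 3. That list had a median of -0.37 (camera, adjusted p = 3.85e-12; adjusted p = 0.102 with an estimated correlation). Light signalling had HY5 higher (0.72), PIF4 (-0.87) and CRY1 (-0.40) lower, and 13 of 16 members not passing (1 higher and 4 lower adjusted over the list alone). Its median was -0.16 (camera, adjusted p = 0.0279; adjusted p = 0.239 with an estimated correlation).

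Of 33 nucleoporins, 3 rose and 1, EDS4 itself, fell, with the same counts adjusted over the list alone. Besides NUP98B, the mRNA export factor RAE1 (AT1G80670) rose from 23.1 ± 0.891 to 46.5 ± 4.34 CPM (log2 change 1.01, SE 0.08) and CG1 rose by 0.40 (SE 0.07). Of 20 RNA export factors, the exportin XPO1B (AT3G03110) rose from 21.9 ± 1.90 to 46.7 ± 3.04 CPM (1.09, SE 0.09) and the adaptor ALY1 rose by 0.50 (SE 0.09), and 18 did not pass. Of the list 4 rose and 1 fell adjusted over the list alone. In edgeR's quasi-likelihood test the adjusted p was 0.00182 for RAE1 and XPO1B, 0.0446 for CG1 and 0.0393 for ALY1. The nucleoporin list did not pass (camera, adjusted p = 0.51; median -0.02, mean 0.03, test pointing up). The export list passed (median 0.05, camera adjusted p = 0.0265) and had an adjusted p = 0.403 with an estimated correlation.

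**Figure D2:**
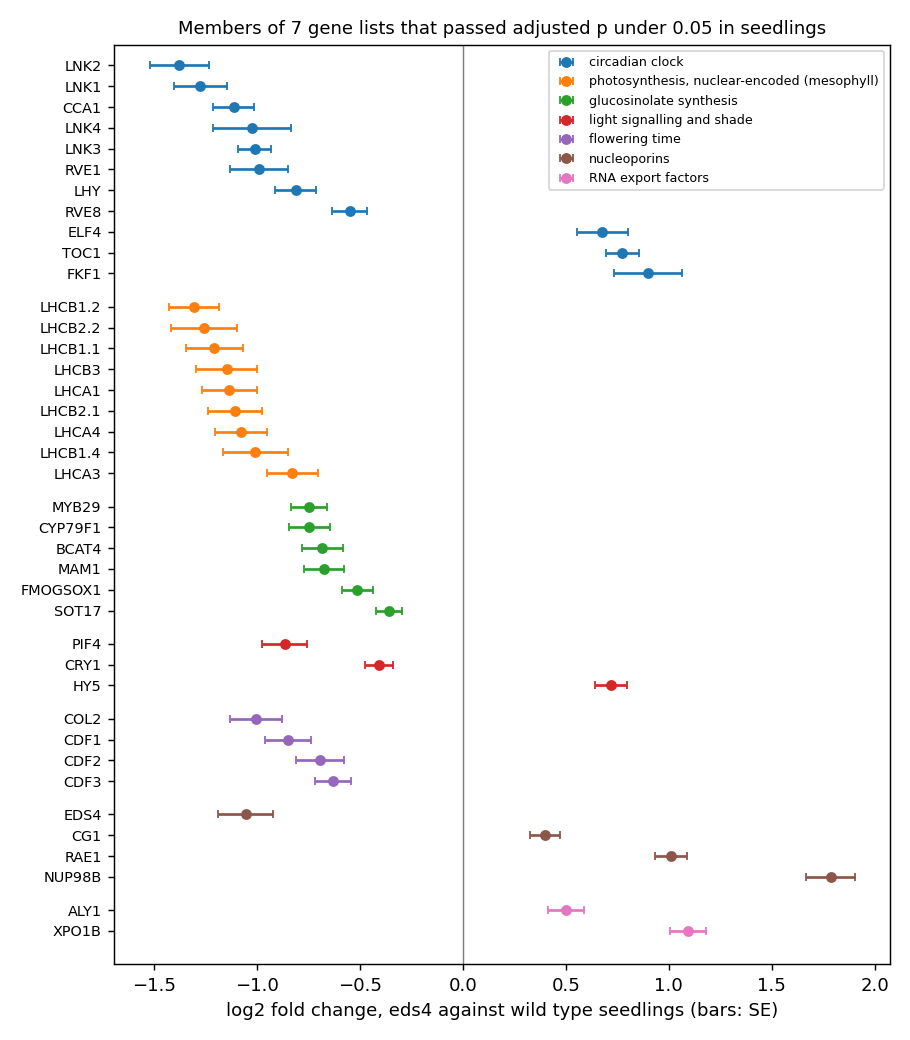
Log2 fold change of eds4 against wild type seedlings (horizontal axis; points with SE bars) for the members of 7 gene lists that passed the test, 1 line per gene and 1 colour per list. Light-harvesting, glucosinolate and flowering genes lie below 0, the clock list lies on both sides, and NUP98B, RAE1 and XPO1B lie at 1.79, 1.01 and 1.09.

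In the other stress and hormone lists few genes passed. Of 22 auxin response genes, IAA29 rose (0.99, SE 0.16) and 0 fell (1 rose and 1 fell adjusted over the list alone). The list's median was 0.33 (camera, adjusted p = 0.00488; adjusted p = 0.403 with an estimated correlation). Of 16 iron deficiency genes, BHLH101 fell (-0.80) and 0 rose (4 and 0 adjusted over the list alone). The median was -0.27 (camera, adjusted p = 0.000208; adjusted p = 0.403 with an estimated correlation). ICS1, the enzyme that makes salicylic acid for defence, fell (-0.51, SE 0.08; edgeR adjusted p = 0.0244) and was the only one of 21 salicylic acid genes to pass, also adjusted over the list alone (camera, adjusted p = 0.721; median 0.02, mean -0.04, test pointing down). In the flavonoid (17), jasmonate (17), cold and abscisic acid (19), phosphate (13), heat shock (17), ribosomal protein (24) and ERF-branch (5) lists 0 members passed. Adjusted over the list alone, 2 heat shock genes rose, 1 ERF-branch gene rose and 2 fell, and 0 changed in the rest. The flavonoid list's median was 0.25 (camera, adjusted p = 0.0221; adjusted p = 0.525 with an estimated correlation). Camera's adjusted p was 0.083 for jasmonate (median -0.17), 0.727 for cold and abscisic acid (-0.10), 0.0558 for phosphate (0.18) and 0.0742 for ribosomal proteins (0.07). It was 0.426 for heat shock, where the median of -0.08 and mean of -0.07 lay below 0 and the test pointed up. It was 0.435 for the ERF branch, where the median of 0.06 lay above 0 and the mean of -1.34 and the test below.

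Primary microRNA transcripts (6 measured, 0 passing) had a median of -0.55 (camera, adjusted p = 0.0145; adjusted p = 0.239 with an estimated correlation), and mitochondria-encoded genes (73, 0 passing) a median of 0.19 (camera, adjusted p = 0.0221; adjusted p = 0.532 with an estimated correlation). Chloroplast-encoded genes (105, 0 passing) had a median of -0.22 (camera, adjusted p = 0.0558). Of the cell type markers, CER1 of wax synthesis fell (-0.85) as the only one of 9 epidermis genes, also adjusted over the list alone, and that list had a median of -0.17 (camera, adjusted p = 0.0265; adjusted p = 0.525 with an estimated correlation). In the guard cell (11), root hair (11), endodermis and stele (11), phloem (9), xylem (6) and dividing cell (12) lists 0 members passed. Adjusted over the list alone, 1 phloem gene fell and 0 others changed. Camera's adjusted p was 0.2 for guard cells (median 0.13) and phloem (-0.12), 0.907 for root hairs (0.02, mean -0.00), 0.502 for endodermis (0.07), 0.918 for xylem (-0.04) and 0.0588 for dividing cells (0.19). In all, 11 of 27 lists passed camera with the preset correlation, 4 higher and 7 lower.

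In wild type nuclei, 25 of 28 photosynthesis and 23 of 24 ribosomal protein genes were lower than in total RNA, while 6 of 20 RNA export factors and 5 of 23 flowering genes were higher. The first 2 lists passed camera with the preset correlation (both with adjusted p = 0.648 with an estimated correlation), and the last 2 did not. MAF2 (AT5G65050), a floral repressor, rose from 44.4 ± 0.235 CPM in total RNA to 327 ± 33.9 CPM in nuclei (log2 ratio 2.88, SE 0.26), and SAC3B (AT3G06290) of the TREX-2 export complex from 47.1 ± 0.468 to 225 ± 19.8 CPM (2.25, SE 0.23). PETE2 (AT1G20340), the plastocyanin gene, fell from 3033 ± 212 to 366 ± 33.4 CPM (-3.05, SE 0.30), and the ribosomal protein gene RPL9C, which has a near-identical copy, from 552 ± 62.7 to 154 ± 21.9 CPM (-1.84, SE 0.25). Adjusted p in edgeR's quasi-likelihood test was 0.000351 for MAF2 and PETE2, 0.000356 for SAC3B and 0.000847 for RPL9C (n = 2 and 2, with the spread pooled over 8 libraries).

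Of 21484 genes, 6582 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3237 higher and 3345 lower in wild type nuclei, and 5599 of these differed at least 2-fold. The count was 3418 without replicate 1 and 3473 without replicate 2 of wild type total RNA, and 47 of 83 named genes that passed did so whichever library was left out. The largest rises were in loci of unknown function: AT2G08986 (0.0656 CPM in total RNA and 223 CPM in nuclei), AT2G07981 (ratio 3619, counting interval 649 to 142988, against 1 count), AT1G40104 (log2 ratio 9.10), AT3G41762 (7.30) and AT3G41761 (7.22). The first 3 are near-identical to each other, and the last 2 to each other and to AT2G01008, so their reads cannot be assigned with certainty. The largest falls were at least 57.6-fold for AT4G35130, 56.5-fold for AT1G76960, 54.1-fold for TED6, a xylem differentiation gene, and 31.8-fold for AT4G15680, each with 0 counts in nuclei. AT1G20590, with a near-identical copy, was lower by a ratio of 122 (interval 21.7 to 4862, 1 count).

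Of 28 photosynthesis genes, 25 were lower in wild type nuclei and 0 higher (28 and 0 adjusted over the list alone), for example PSBS (-3.25), PSAD1 (-2.59) and LHCB4.1 (-2.55). The median was -2.26 (camera, adjusted p = 6.23e-19; adjusted p = 0.648 with an estimated correlation). Of 24 ribosomal protein genes, 23 were lower and 0 higher (24 and 0 adjusted over the list alone), such as RPL27AC (-1.74) and RPS15AA (-1.93), with a median of -1.08 (camera, adjusted p = 3.23e-09; adjusted p = 0.648 with an estimated correlation). Markers of epidermis had 6 of 9 lower, led by LTP1 (-2.37), and those of phloem 5 of 9, led by AHA3 (-1.76), with 0 higher in either (8 and 7 lower adjusted over the list alone). Camera's adjusted p was 0.00123 for epidermis and 0.0226 for phloem, and both had adjusted p = 0.648 with an estimated correlation. Median log2 ratios of the other cell type lists were 2.41 for root hair, 1.86 for endodermis and stele, -0.70 for dividing cells, -0.90 for guard cells and -1.61 for xylem. For phloem and epidermis they were -0.96 and -1.06. A different recovery of cell types in the sorted nuclei cannot be told apart from these ratios. Of 66 chloroplast-encoded genes, 10 were lower and 2 higher (7 and 2 adjusted over the list alone). The list's median was -1.30 (camera adjusted p = 0.0122, or 0.709 with an estimated correlation). The chloroplast share of counts went the other way. It was 1.33 and 4.21% in wild type nuclei, against 0.661 and 0.731% in wild type total RNA. The lower median of the list therefore does not show that wild type nuclei held less chloroplast RNA.

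Lists that did not pass as a whole also held members that did. Of 20 RNA export factors, 6 were higher in wild type nuclei, among them SAC3A (1.81), ALY3 (2.36) and MOS11 (1.68), and 1 was lower (6 and 1 adjusted over the list alone). Of 33 nucleoporins, 5 were higher and 8 lower (6 and 9 adjusted over the list alone), with GLE1 higher (1.26) and NUP96 (-1.67), NUP155 (-1.33) and NUP93A (-1.09) lower. Of the flowering genes 5 of 23 were higher, with MAF3 at 2.30 and FLM at 2.18, and 1 was lower (the same counts adjusted over the list alone). Of the clock genes 5 of 27 were higher, with PRR7 at 2.49, LNK2 at 2.24 and ELF3 at 1.81, and 4 lower (5 and 5 adjusted over the list alone). Camera's adjusted p was 0.126 for RNA export, 0.402 for nucleoporins, 0.155 for flowering and 0.653 for the clock. Of 17 cold and abscisic acid genes 7 were lower, led by COR15B (-2.98), and 1 higher (7 and 3 adjusted over the list alone). Of 20 glucosinolate genes 7 were lower, such as CYP79B3 (-1.59) and MAM1 (-1.93), and 0 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.107). Of 10 endodermis and stele genes 3 were higher, such as CASP2 (3.39) and CASP1 (2.75), and PHO1 (-1.32) was lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.282).

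In eds4, 24 of 28 photosynthesis and 23 of 24 ribosomal protein genes were lower in nuclei, and 12 of 27 clock genes were higher, among them LNK2, PRR7 and ELF3, which were also higher in wild type nuclei. LNK2 rose from 48.6 ± 13.8 CPM in total RNA to 540 ± 133 CPM in nuclei (log2 ratio 3.47, SE 0.33), PRR7 by a log2 ratio of 3.28 (SE 0.42) and CCA1 from 4.14 ± 0.915 to 40.5 ± 36.2 CPM (3.29, SE 0.63), a spread set by replicates at 14.9 and 66.0 CPM. The export genes SAC3B (2.13), SAC3A (2.21), MOS11 (2.72) and ALY3 (1.66) and the floral repressors MAF2 (2.43), MAF3 (1.93) and FLM (1.83) were also higher, and PETE2 (-3.21), PSBS (-2.97) and RPL9C (-2.16) lower. EDS4 had a log2 ratio of 0.79 in eds4 (SE 0.26, edgeR adjusted p = 0.0441) and of -0.63 in the wild type (SE 0.26, edgeR adjusted p = 0.0908). The first did not pass edgeR's test with any one of the 4 eds4 libraries left out (highest adjusted p = 0.311). Adjusted p in edgeR's quasi-likelihood test was 0.000358 for LNK2, MAF2 and PETE2, 0.000577 for PRR7 and 0.00361 for CCA1.

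In eds4, 6357 of 21484 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3348 higher and 3009 lower in nuclei, 5518 of them at least 2-fold. The count was 3729 without replicate 1 and 3731 without replicate 2 of eds4 total RNA, and 53 of 90 named genes that passed did so whichever library was left out. Of these genes 4668 passed in both genotypes, 2436 higher in both, 2230 lower in both and 2 in opposite directions, where independent lists would share 504 and 468. Across genes, which are not independent replicates, the ratios of the 2 genotypes had a Pearson correlation of 0.631 and a Spearman correlation of 0.733. The largest rises were AT2G08986 (at least 429-fold higher), AT1G40104 (at least 240-fold) and AT2G07981 (at least 110-fold), the near-identical loci named above, then the F-box gene AT5G10340 (log2 ratio 5.32) and AT3G41762 (5.30). The largest falls were at least 187-fold for AT3G16670, 91.0-fold for TED6, 68.0-fold for DMP2, 62.6-fold for AT5G07080 and 54.7-fold for AT2G27140.

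**Figure D3:**
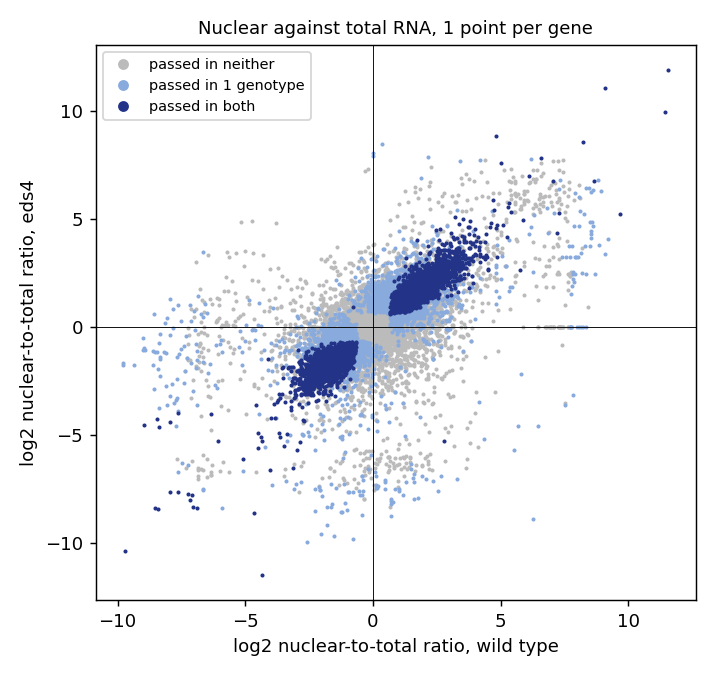
Log2 nuclear-to-total ratio in eds4 (vertical axis) against the wild type (horizontal axis), 1 point per gene for 21484 genes, coloured by whether the gene passed in both genotypes, in 1 or in neither. The 4668 genes that passed in both lie along the diagonal, with 2 in opposite directions.

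Of 27 clock genes, 12 were higher and 1 lower in eds4 nuclei (13 and 1 adjusted over the list alone), with a median of 1.31 (camera, adjusted p = 0.00182; adjusted p = 0.698 with an estimated correlation). Of 23 flowering genes, 7 were higher and 1 lower, the same counts as adjusted over the list alone, with COL2 at 2.15 and a median of 0.76 (camera, adjusted p = 0.0466; adjusted p = 0.462 with an estimated correlation). Photosynthesis had 24 of 28 lower (25 adjusted over the list alone; median -2.28, camera adjusted p = 1.49e-19) and ribosomal proteins 23 of 24, the same adjusted over the list alone (median -1.48, camera adjusted p = 3.99e-14), with RPS15AA at -2.47. Phloem had 5 of 9 lower by either count (median -0.90, camera adjusted p = 0.00131). Each of these 3 had adjusted p = 0.447 with an estimated correlation. Xylem had 4 of 6 lower and epidermis 4 of 9, by either count, with XCP2 at -3.08 and LTP1 at -2.43. Camera's adjusted p was 0.0366 and 0.0388, and the adjusted p = 0.447 and 0.698 with an estimated correlation.

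Some organelle transcripts were lower in eds4 nuclei than in eds4 total RNA. Of 66 chloroplast-encoded genes, 21 were lower and 0 higher (27 and 0 adjusted over the list alone), with a median of -3.40, or -3.05 with 20 members at their floor (camera, adjusted p = 1.21e-09; adjusted p = 0.447 with an estimated correlation). Of 29 mitochondria-encoded genes, 6 were lower (0 adjusted over the list alone), with a median of -5.41, or -2.12 with 18 members at their floor (camera, adjusted p = 0.000463; adjusted p = 0.653 with an estimated correlation). The eds4 nuclei had chloroplast shares of 0.543 and 0.259%, against 0.632 and 2.05% in eds4 total RNA. Mitochondrial shares were 0.0135 and 0.00789% in eds4 nuclei, against 0.0130 and 0.0337%. RHS19, a root hair gene, was at least 13.8-fold lower. Outside the lists that passed, GLE1 (1.35) and CG1 (1.67) were higher among 7 nucleoporins that rose, NUP96 (-1.51) and NUP50A (-1.50) were lower among 8 that fell, and PIF5 (2.14) and MYBL2 (2.52) were higher.

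Whether the nuclear-to-total ratio differed between the genotypes was tested by the interaction term. EDS4 had the difference 1.43 on the log2 scale (SE 0.37, edgeR unadjusted p = 0.00310, adjusted p = 0.771), higher in eds4. In edgeR's quasi-likelihood test 0 of 21484 genes passed, with a smallest adjusted p of 0.472, and 1252 had an unadjusted p under 0.05. DESeq2 called 40 and limma-voom 0. On simulated data the interaction test recovered 16.7% of 4-fold and 0% of 2-fold differences, so differences of that size were mostly not detectable with these samples.

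As groups, clock genes had a higher nuclear-to-total ratio in eds4 than in the wild type, with a median difference of 1.11 over 27 genes (camera, adjusted p = 2.72e-07; adjusted p = 0.529 with an estimated correlation). Heat shock genes (15) had a median difference of 1.08 (camera, adjusted p = 0.00248; adjusted p = 0.36 with an estimated correlation), cold and abscisic acid genes (17) of 0.65 (camera, adjusted p = 0.0123; adjusted p = 0.529 with an estimated correlation), ERF-branch genes (7) of 0.57 (camera, adjusted p = 0.0378; adjusted p = 0.36 with an estimated correlation) and epidermis genes (9) of 0.30 (camera, adjusted p = 0.0401; adjusted p = 0.536 with an estimated correlation). Lower in eds4 were ribosomal proteins (24; median -0.31, camera adjusted p = 0.0123; adjusted p = 0.648 with an estimated correlation) and endodermis genes (10; -1.19, camera adjusted p = 0.0356; adjusted p = 0.633 with an estimated correlation). Root hair genes (7; -3.24, camera adjusted p = 1.93e-06), chloroplast genes (66; -2.30, or -1.84 with 23 members at their floor, camera adjusted p = 1.07e-11) and mitochondrial genes (29; -4.99, or -2.71 with 19 at their floor, camera adjusted p = 3.84e-13) were also lower. Each of these 3 had adjusted p = 0.36 with an estimated correlation. Adjusted over the list alone, 2 ERF-branch genes were higher, and 6 mitochondrial and 1 root hair gene lower; 0 members passed over all genes. These lists moved with the nuclei libraries' shares of rRNA (2.79 and 11.2% in the wild type, at most 1.59% in eds4) and of chloroplast transcripts (1.33 and 4.21%, against 0.543 and 0.259%). Mitochondrial shares were 0.0236 and 0.203% in replicates 1 and 2 of wild type nuclei, against 0.0135 and 0.00789% in eds4 nuclei. For the cell type lists, a different mix of cells in the sorted nuclei cannot be told apart either. The 10 lists became 1 without wild type nuclei replicate 2, 5 without eds4 nuclei replicate 1, and 3 with only replicate 1 of each nuclei group, a fit chosen after seeing the data.

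In total RNA of the distribution experiment the genotypes differed in AT3G01345 (chromosome 3, 129138 to 130749), a gene of unknown function. It stood at 198 ± 0.543 CPM in the wild type and had 2 counts in eds4 (ratio 4984, counting interval 1379 to 41156; edgeR adjusted p = 1.7e-05, n = 2 and 2). It was the only gene of 21484 to pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 605 had an unadjusted p under 0.05, DESeq2 called 16 and limma-voom 0. Of the 291 genes that changed in profiling seedlings and were measured here, 219 (75.3%) had the same sign in total RNA, with a Pearson correlation of 0.663 across those genes. NUP98B stood at 5.52 ± 0.841 CPM in the wild type and 29.5 ± 11.2 CPM in eds4 (2.42, SE 0.32, edgeR adjusted p = 0.159).

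Jasmonate genes (16) lay higher in eds4 total RNA (median 0.60, camera adjusted p = 0.000454), as did glucosinolate (20; 0.21, camera adjusted p = 0.0447) and phloem genes (9; 0.29, camera adjusted p = 0.0308), and clock genes (27) lay lower (-0.33, camera adjusted p = 0.0179). Each had adjusted p = 0.885 with an estimated correlation, and 0 members passed, also adjusted over the list alone. The glucosinolate list pointed the other way in profiling seedlings. The photosynthesis list, lower there, had a median of -0.01 in total RNA, with 0 of 28 members passing, also adjusted over the list alone (camera adjusted p = 0.849). The iron deficiency list, also lower there, had a median of 0.34 (camera adjusted p = 0.355). TOC1, higher in eds4 there, stood at 300 CPM in wild type and 193 CPM in eds4 total RNA (-0.64, SE 0.28, edgeR adjusted p = 1), and CCA1 at 4.30 and 4.14 CPM. The wild type itself stood at 52.5 CPM of TOC1 and 159 CPM of CCA1 in profiling seedlings. The experiments therefore differed in the levels of these clock genes, which limits the comparison of lists between them. The number of lists was 7 and 2 without wild type total replicates 1 and 2, and 11 without eds4 total replicate 1.

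In nuclei, NUP98B and RAE1 were again higher in eds4. Also higher there were ORA59 and 2 of 27 clock genes, LNK3 and LNK4, both of which were lower in eds4 profiling seedlings. Of 14 flavonoid genes 2 were lower (camera adjusted p = 0.19 for the flavonoid list). NUP98B rose from 10.0 ± 0.206 to 42.0 ± 2.71 CPM (log2 change 2.07, SE 0.32) and RAE1 from 19.2 ± 3.12 to 62.4 ± 14.4 CPM (1.70, SE 0.27). LNK4 of the clock rose from 10.2 ± 0.608 to 49.1 ± 6.05 CPM (2.27), LNK3 from 0.115 ± 0.0252 to 12.8 ± 11.8 CPM, and ORA59, a regulator of ethylene and jasmonate defence, from 12.6 ± 0.754 to 83.6 ± 33.5 CPM (2.73). CHS, the first enzyme of flavonoid synthesis, fell from 51.8 ± 4.11 to 11.3 ± 1.43 CPM (-2.20, SE 0.33), and the flavonoid hydroxylase F3PH was at least 46.1-fold lower. Adjusted p in edgeR's quasi-likelihood test was 0.04 for NUP98B, 0.042 for RAE1, 0.0444 for LNK4, 0.0419 for LNK3, 0.0251 for ORA59, 0.0399 for CHS and 0.0438 for F3PH (n = 2 and 2).

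Of 21484 genes, 78 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 67 higher and 11 lower in eds4 nuclei, and 3039 had an unadjusted p under 0.05. Further large rises were AT2G38830 (ratio 37.3, interval 12.5 to 184), AT3G23450 (log2 change 4.28), AT1G27640 (4.11) and the zinc and iron transporter IRT3 (3.93). Further large falls were AT3G01345 (-8.43, SE 0.46), AT5G07080 (at least 32.8-fold lower), the peroxidase gene AT2G41480 (ratio 243, interval 43.2 to 9641) and the glycine-rich protein gene AT4G30460 (-4.57). With DESeq2's size factors 32 genes passed (23 higher, 9 lower), with the rRNA loci left out 36 (27 higher, 9 lower), and with DESeq2's own test 860. The count was 1 without either wild type nuclei library, 181 and 26 without eds4 nuclei replicates 1 and 2, 3 in a fit of the nuclei alone and 239 with only replicate 1 of each nuclei group. Of the 15 named genes that passed, AT3G01345 was the only one to pass whichever nuclei library was left out. Of the 291 genes changed in profiling seedlings, 173 (59.5%) had the same sign in nuclei. Of these 291, 9 passed in both as higher and 1 as lower, where independent lists would share 0.528 and 0.0662. Another 3, LNK3 and LNK4 among them, passed in opposite directions.

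By list, eds4 nuclei had 2 of 27 clock genes higher (6 adjusted over the list alone), with a median of 0.54 (camera, adjusted p = 0.00205). Glucosinolate genes (20; 0.58, camera adjusted p = 0.00205), jasmonate genes (16; 0.54, camera adjusted p = 0.00605) and epidermis genes (9; 0.80, camera adjusted p = 0.00441) also lay higher, with 0 members passing and 0, 0 and 3 adjusted over the list alone. Primary microRNA transcripts (6; -1.06, camera adjusted p = 0.0406), chloroplast genes (66; -2.05, or -1.75 with 23 at their floor, camera adjusted p = 7.5e-08) and endodermis genes (10; -1.14, camera adjusted p = 0.00693) lay lower, with 0 members passing; adjusted over the list alone 0, 7 and 3 were lower, and 1 endodermis gene was higher. Each of these 7 had adjusted p = 0.636 with an estimated correlation. Heat shock genes (15; 1.15, camera adjusted p = 0.00693) lay higher, and mitochondrial genes (29; -5.58, or -2.77 with 19 at their floor, camera adjusted p = 6.55e-09) and root hair genes (7; -3.20, camera adjusted p = 7.4e-05) lower, each with adjusted p = 0.579 with an estimated correlation and 0 members passing; adjusted over the list alone 1 was higher, 10 lower and 3 lower. The rRNA, chloroplast and mitochondrial shares given for these libraries moved with these lists: all were higher in wild type nuclei. The 10 lists became 16 without wild type nuclei replicate 1, 3 without its replicate 2, 3 without eds4 nuclei replicate 1, and 0 with only replicate 1 of each nuclei group.

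The genotype effect in whole seedlings was compared between the experiments in a fit of 11 libraries. AT3G01345 had a fitted difference of 12.48 (edgeR adjusted p = 0.000449), which rests on 2 counts in eds4 total RNA (ratio 4984 there, interval 1379 to 41156). Its mean was 0.197 CPM in wild type and 0.257 CPM in eds4 seedlings of the profiling experiment, at most 0.401 CPM in any wild type library there, and 198 CPM in wild type total RNA. AT3G45990, a cofilin family gene (chromosome 3, 16900778 to 16904136), passed with a fitted difference of -8.21 (edgeR adjusted p = 0.00577), whose size is not measurable because wild type total RNA had 0 counts. In total RNA it was at least 19.7-fold higher in eds4, with 5.21 and 6.21 CPM in wild type and eds4 profiling seedlings, 0 CPM in wild type total RNA and 1.04 CPM in eds4 total RNA. These 2 of 22525 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 2116 had an unadjusted p under 0.05, DESeq2 called 212 and limma-voom 1. The count was 5 without eds4 seedlings replicate 3, 4 and 28 without wild type total replicates 1 and 2, and 20 and 14 without eds4 total replicates 1 and 2. For EDS4 the difference was 0.25 (edgeR adjusted p = 0.823).

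**Figure D4:**
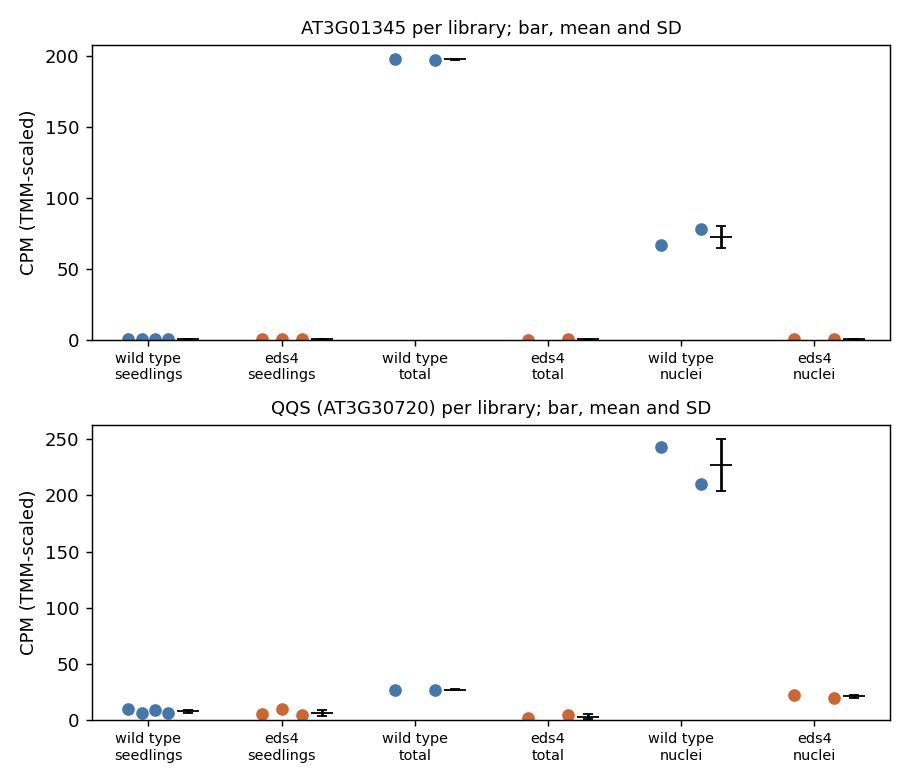
Levels of AT3G01345 (upper panel) and QQS (lower panel) in CPM (vertical axes, from 0) in each of the 15 libraries, by group; points are libraries, and bars are group means with SD. Both genes are shown by choice after their values were seen; AT3G01345 stands at 198 CPM in wild type total RNA and 72.3 CPM in wild type nuclei, and at 0.197 and 0.257 CPM in the seedlings of the profiling experiment.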

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

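The tests of technical explanations and of other splits were chosen after the results were seen, except that of less cytoplasmic RNA in the eds4 nuclei libraries; the tests between groups were fixed beforehand.

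Of 54 values given Dixon's test in the wild type seedlings (n = 4), 3 lay past its critical value, and chance alone gives about 1 in 20. Replicate 3 had a lower share of counts in its 10 highest genes (6.18% against 7.06 to 7.20%; gap over range 0.860) and a lower BCAT4 level (180 CPM against 215 to 217 CPM; 0.932). Replicate 2 had a higher level of the pseudogene AT5G35935 (9.54 CPM against 4.56 CPM in the lowest library; 0.832).

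A difference between groups in the effect of the same contrast brought out the next results. The genotype effect differed between experiments for AT3G01345 (fitted value 12.48, resting on 2 counts in eds4 total RNA; ratio there 4984, interval 1379 to 41156) and AT3G45990 (fitted value -8.21, with 0 counts in wild type total RNA; at least 19.7-fold higher in eds4 there). In the distribution experiment the nuclear-to-total ratio of EDS4 differed between genotypes by 1.43 (edgeR unadjusted p = 0.00310 for this locus named beforehand). For 10 lists the nuclear-to-total ratio differed between genotypes by camera with the preset correlation, and for 0 with an estimated correlation. Their median log2 differences were 1.11 (circadian clock), 1.08 (heat shock), 0.65 (cold and abscisic acid), 0.57 (ERF branch), 0.30 (epidermis), -0.31 (ribosomal proteins), -1.19 (endodermis), -2.30 (chloroplast; -1.84 with 23 of 66 members at their floor), -3.24 (root hair) and -4.99 (mitochondria; -2.71 with 19 of 29 at their floor). Without wild type nuclei replicate 2 the 10 lists became 1.

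EDS4 was lower in eds4 in whole-seedling RNA of both experiments and not in nuclei. Whether nuclei show less of any genotype effect could not be decided. The 129 other genes higher in eds4 seedlings that kept their direction in total RNA had a median change of 0.591 there. In nuclei it was 0.982, and 0.790 to 0.986 with 1 nuclei library left out. But an upward shift in eds4 nuclei would give this too, and the genes lower in seedlings, given next, did not fall there at the median. Whether falls in general are not seen in nuclei cannot be told apart from the spread of the libraries: for 89 such falls the median change signed by direction was -0.168 in nuclei and 0.558 in total RNA, but -0.549 to 0.491 with 1 nuclei library left out, the highest without eds4 nuclei replicate 1. Under 3 other scalings the difference in the ratio of EDS4 stayed at 1.33 or more (SE 0.369), so it did not rest on the choice among these. All 3 set the bulk of genes to no change, so they cannot decide whether scaling was the cause. A swap or mix of eds4 nuclei with the wild type nuclei of this experiment is argued against. The eds4 nuclei held at most 0.336% of the AT3G01345 level of those wild type nuclei. AT3G01345 was also near 0 in wild type profiling seedlings, so it does not mark the eds4 genotype, and other mislabelling was not tested. A retention of the mutant transcript in the nucleus was not tested.

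AT3G01345 was high in the wild type of the distribution experiment (198 CPM in total RNA, 72.3 CPM in nuclei) and near 0 in every other group; QQS, picked after its values were seen, stood at 26.7 CPM in wild type and 2.80 CPM in eds4 total RNA, and at 7.42 and 6.36 CPM in profiling seedlings. A difference in sampling or extraction that acts alike on both genotypes is argued against, since eds4 total RNA, prepared alike, held 0.0230% of the wild type level. One that acts only in the wild type cannot be told apart, because eds4 stood near 0 in both experiments. Reads of a near-identical copy are argued against, since the reference held 0 near-identical transcripts. A difference between the wild type seed stocks of the experiments stays open, is confounded with experiment, and no biological explanation was tested. The labels give the strain Col-0 for both, although among the titles only those of the profiling wild type name it. The count columns of the distribution wild type are named Ctrl.

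In nuclei 78 genes differed between the genotypes, 67 of them higher in eds4. Less cytoplasmic RNA in the eds4 nuclei libraries cannot be told apart from a change of the genes: 66.7% of the 78 moved the way their nuclear-to-total ratio points (46.2% of all genes), between the bounds set beforehand of 80% and 60%. Without the rRNA loci the median change of these genes was 2.09, against 2.16 with them, and the median SE 0.324, against 0.326. This cannot decide whether scaling was the cause, since TMM trims extreme loci and could hardly move with the rRNA loci left out. Even so the calls went from 78 to 36: 42 of the 78 had an adjusted p above 0.04 in edgeR's quasi-likelihood test, the median unadjusted p moved from 8.21e-05 to 0.00011, and the highest adjusted p of the 78 by edgeR became 0.0640. A change of transcription or export in eds4 was not tested.

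For the seedlings, chance cannot be excluded by splitting the libraries otherwise: of 35 splits into 4 and 3, 3 gave as many genes, the real one (297) included, and the highest other gave 553. That split set wild type replicates 3 and 4 with eds4 replicate 3 against the rest, the 3 libraries highest on the first principal component, which points to a structure of the samples that the count of splits does not allow for. The other, with 517, set wild type replicate 1 with eds4 replicates 1 and 2, the 3 libraries lowest on it (-22.2, -37.1 and -33.9), so it follows the same structure. With a term for the replicate sets 868 genes passed, and within replicates 1 and 2 alone 525. In the separate total RNA libraries 219 of 291 of these genes had the same sign (Pearson correlation 0.663).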

How the results depend on the processing

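Besides the alternatives fixed beforehand, the replicate set, rRNA and replicate 1 fits were chosen after the results were seen. Of 3309 comparisons of a named gene's value with an alternative, 2844 kept direction and side of the threshold, 462 were weaker, 2 stronger and 1 reversed. The reversed value was EDS4 in nuclei, -0.10 without wild type nuclei replicate 1 and 0.27 without its replicate 2, never past the threshold. No list that passed turned direction with organelle genes or nuclear rRNA loci left out, and no setting failed to run. The lists were not tested with DESeq2's size factors, DESeq2's test, limma-voom or no filter on low counts. Where a count moved, the cause was not tested. With 1 library left in a group, that library is assumed to vary like the others. The nuclei libraries had the lowest depth, which limits genes near 0 counts.

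Genes changed in seedlings numbered 1047 with DESeq2's test, 88 with 11 libraries in one fit, 868 with the replicate set term, 525 within replicates 1 and 2, and 42 to 462 with 1 library left out. Nuclear against total RNA gave 3418 to 5605 genes in the wild type and 3729 to 5602 in eds4 with 1 library left out. The nuclear-to-total difference gave 40 genes with DESeq2's test and 226 with no filter on low counts. In total RNA the count was 16 with DESeq2's test, 0 with limma-voom, 95 with no filter and 1 to 2 with 1 library left out. In nuclei it was 32 (23 higher, 9 lower) with DESeq2 size factors, 860 with DESeq2's test, 1167 with no filter, 3 with only the groups compared, 36 (27 higher, 9 lower) without rRNA loci, against 67 higher and 11 lower in the first fit. It was 239 with only replicate 1 of each nuclei group, 42 of them among the 78, and 1 to 181 with 1 library left out. Between experiments it was 212 with DESeq2's test, 1 with limma-voom, 15 with no filter and 2 to 28 with 1 library left out.

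With an estimated inter-gene correlation 0 lists passed in each of the 6 comparisons. With fry 6 passed in seedlings, 0 in the nuclear-to-total difference, 0 in total RNA and 1 in nuclei. With 1 library left out the numbers were 1 to 13 in the difference, 2 to 11 in total RNA and 3 to 16 in nuclei; with only replicate 1 of each nuclei group they were 3, 2 and 0.

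A replicate block was fitted, although the labels do not say whether the numbers pair the samples and the values do not settle it. In seedlings the correlations of same-numbered deviations were 0.395, -0.0941 and 0.378, and not every sample correlated best with its own number. In the distribution experiment they were 0.129 in the wild type and -0.0295 in eds4 between total RNA and nuclei. Between genotypes they were 0.0935 in total RNA and 0.105 in nuclei. With the block 414 genes passed in seedlings, 7323 and 7034 in nuclei against total RNA of wild type and eds4, 0 in their difference, 3 in total RNA and 248 in nuclei; lists numbered 11, 6, 9, 10, 3 and 11.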

Other observations

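The test of nuclear transport genes was chosen after the result was seen; the tests on introns and non-coding RNAs were set beforehand.

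Some genes whose products carry proteins through the nuclear pore rose in eds4 seedlings. Of 21 measured importin, exportin, transportin, Ran and nuclear transport factor genes, 5 rose and 0 fell, 13 lay above 0 and the median was 0.06: the Ran GTPases RAN-1 (1.29) and RAN2 (0.97), the exportin XPO1B (1.09), the transport factor NTF2B (0.74) and AT1G69680 (1.28), annotated as a putative Ran guanine nucleotide release factor. The group was assembled from product names after the seedling values had been seen, its definition was corrected once, and the total RNA values had also been seen, so a rise of the group is a hypothesis that these libraries cannot test. In total RNA of the distribution experiment 15 of 22 members were higher in eds4, with a median of 0.29 (camera p = 1.12e-05, and p = 0.0122 with an estimated correlation), and the hypothesis stays open. In nuclei the median was 0.27 (camera p = 0.0235, and p = 0.0882 with an estimated correlation).

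Nuclear-to-total ratios of classes of RNA in the wild type are given as values, with no test between classes. Median log2 ratios were 1.93 for 31 microRNA genes (10 higher in nuclei), 2.71 for 28 snoRNA genes (13 higher), 3.65 for 409 pseudogenes (3.03 with 195 at their floor) and -0.04 for 20319 protein-coding genes. A locus near 0 counts in total RNA of both genotypes passes the filter on low counts only through nuclei, which can raise such medians. For 205 lncRNA genes, 60 of them higher and 18 lower, the median was 0.38. Whether lncRNAs are more nuclear than protein-coding genes by at least 0.5 stays open: the difference was 0.418, and 0.336 to 0.570 with 1 wild type library left out. Whether the ratio rises with the intron share of the locus at a Spearman correlation of 0.1 or more stays open too: it was 0.0832 in the wild type, 0.0738 to 0.101 with 1 library left out, and 0.00214 in eds4. The median was -0.42 for 3334 genes without introns and 0.01 for 2380 genes with over 50% intron.

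Of the clock genes, 2 picked after their values were seen, and not tested, stood at different levels in the 2 experiments: CCA1 at 159 CPM in wild type and 73.4 CPM in eds4 profiling seedlings and at 4.30 and 4.14 CPM in total RNA, and TOC1 at 52.5 and 89.7 CPM and at 300 and 193 CPM.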
